A study of Arabidopsis thaliana with 4 samples.

How the data were processed

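The series holds 4 RNA sequencing libraries of whole seedlings, 2 of a control line and 2 of the fip1-2 mutant, grouped by the genotype given in the labels with replicate numbers from the sample titles. The growth protocol in the labels gives a growth time without its unit in Murashige and Skoog medium. The labels disagree on the assay. The series' design text names sequencing of poly(A) tags, which reads the 3' ends of transcripts, while the extract protocol describes mRNA selected with oligo(dT) beads and fragmented before cDNA synthesis and Illumina sequencing. The trend of the log2 fold change with transcript length is reported with the results. The protocol describes no step that marks the strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart.

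Per the submitters' processing notes, CASAVA 1.4, FastQC, HISAT2, HTSeq and edgeR were used, with no role or order given; the genome build, annotation and counting options are not given in the sources used here. The deposited file holds a signal per gene in each library, that is read counts per gene that the authors divided by one size factor per library, per the file name and the values. Each column is a whole-number multiple of its smallest value above 0, so whole reads were recovered by division. All values (100%, within 1e-06) came out whole. The recovered totals ran from 20874114 to 21104606 reads per library, and they limit the precision of every value together with the spread between replicates. The median standard error of a log2 fold change was 0.094. The file lists 27654 genes, of which 4108 had no read in any library.

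The values were used as deposited, without rescaling. Genes with a mean of at least 10 over the 4 libraries were tested on log2(value + 2) with limma 3.58.1 (lmFit, eBayes with a variance trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and genotype was the only term in the model. Since whole reads could be recovered, edgeR 4.0.16 (TMM factors, quasi-likelihood test) was also run on them and called 10820 genes, 10652 of them shared with limma, at a biological coefficient of variation of 0.0439. The 18 gene lists, the rule for named genes and the alternatives, except one named below, were fixed before the data were examined. The lists hold 305 genes in all, of which 296 carry the listed name in the reference; the others are given by identifier. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 18 lists. With a correlation estimated from these libraries, camera takes its degrees of freedom from the residuals, here 2, and estimated correlations from -0.111 to 0.589 over the lists; it called none of the 10 lists called with the preset one. It gave 0 lists also at an unadjusted p under 0.05, while fry, which asks only whether the members of a list move one way on balance, called 10 (2 of camera's calls lost and 2 others gained). Gene names come from the TAIR10.1 RefSeq annotation, in which 27444 identifiers (99.2%) were found; the other 210 are organelle-encoded, 88 in the chloroplast and 122 in the mitochondrion. The digit after AT in an identifier is the chromosome. No coordinates are given because the build behind the file is not given in the sources used here. Transcript length and GC content are those of the longest annotated transcript.

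The rule for the genes named takes FIP1 and SKP2B; the 10 largest rises and 10 largest falls among called genes with a mean of at least 100 and both fip1-2 libraries on one side of both control libraries; and from each list up to 4 members with the smallest p, 89 genes in all. Genes named outside it, AT2G28160, LHCB1.2, LHCB1.3, SESA1, SESA2 and SESA3 in the report and others in the closing section, were chosen after their values were seen. A fold against a group without reads is a lower bound with a floor of 3 reads per library, and with 1 to 3 reads the ratio has an exact 95% binomial interval; both cover counting error only, since PCR copies are not independent molecules. Replicates were compared before they were averaged. They differed by more than sampling noise (chi-square per gene 3.03 in control and 2.79 in fip1-2, over 19788 and 19893 genes) and were counted as separate libraries.

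The calls were tested on simulated data, with counts drawn for the real genes from the mean levels and dispersions of these libraries and 200 genes changed by known folds in the fip1-2 against control comparison. Over 19934 genes tested, limma recovered 70% of genes changed 1.5-fold, 88% of those changed 2-fold and 96% of those changed 4-fold, and called 5 of 19735 unchanged genes. Far more genes were called in the data than were changed here, so these shares do not measure the sensitivity of the real comparison. Each gene was given the dispersion usual for its level, so wide replicate spread of single genes was not simulated. When a trend with transcript length was added to the simulated values, 4286 unchanged genes were called, and 4 after the trend was removed. The added trend was a straight line in log2 length, a form that the removal fits. Its success was therefore fixed in advance and does not show how well the real trend is removed. Also tried were other pseudocounts, filters, scalings, variance priors and thresholds, a replicate block, each library left out in turn, edgeR and DESeq2 1.42.0 on the recovered reads, and other list tests; removal of the length and GC trend with natural splines of 5 degrees of freedom was added later. Figures were drawn with matplotlib 3.10.9 and permutation tests run with numpy 2.4.6 and Fisher's exact tests with scipy 1.17.1 in Python 3.11.15.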

Results

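Polyadenylated RNA was profiled in whole Arabidopsis thaliana seedlings of the Columbia ecotype. The control line carried a reporter in which the promoter of SKP2B drives the GUS enzyme, and it was compared with fip1-2, a mutant named for FIP1, a factor of the machinery that cleaves and polyadenylates messenger RNA. Each group had 2 libraries. Reads assigned to genes came to 21056064 and 21104606 in the control libraries and to 20908391 and 20874114 in the fip1-2 libraries, and 22278, 22259, 22545 and 22509 genes had at least 1 read in them. The correlation of log2 values between replicates was 0.994 in both groups, and between groups it ran from 0.949 to 0.956. The series title ties the study to plant development and to root responses to abiotic stress, and the comparison asks which transcripts differ in seedlings of the mutant. Values are normalised read counts given as mean ± SD with n = 2 per group, and fold changes are on the scale of log2(value + 2), which understates the change of weakly expressed genes. Nothing in the labels says that replicates came from separate cultures, so the spread between libraries behind the p-values may be technical. In limma the variance of each gene is also drawn toward that of genes of like level. A gene whose own replicates differ widely can therefore still pass.

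The transcript of FIP1 itself, listed as FIP1[V] (AT5G58040, chromosome 5), was higher in the mutant. It stood at 1854 ± 82.4 in control and 5181 ± 51.2 in fip1-2 seedlings, a 2.79-fold difference (log2 fold change 1.48 ± 0.05 SE, limma adjusted p = 2.98e-11). Both fip1-2 libraries, at 5217 and 5145, lay above both control libraries, at 1796 and 1912. The labels do not say what kind of mutation fip1-2 is, and a total over the gene does not show which part of it the reads came from, so the level checks neither the loss nor the presence of a working product. SKP2B (AT1G77000), whose promoter drives the reporter of the control line, stood at 246 ± 1.63 in control and 254 ± 0.570 in fip1-2 (log2 fold change 0.05 ± 0.10 SE, limma adjusted p = 0.716), and its log2 fold change ran from 0.04 to 0.11 over its alternatives without passing.

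Genes of seed reserves, iron uptake and root hairs were among those higher in fip1-2, and genes of auxin response among those lower. Of 19931 genes tested, 5384 were higher and 5342 lower in fip1-2, together 53.8%. Most of these differences were small. The median size among the 10726 genes was 1.39-fold, 924 genes were at least 2-fold higher and 749 at least 2-fold lower, and at 4-fold the counts were 275 and 108. The log2 fold change rose with the length of the transcript, with a Spearman correlation of 0.299 across genes, which are not independent replicates. Its median was -0.25 in the tenth of genes with the shortest transcripts and 0.26 in the tenth with the longest. After a trend with transcript length and GC content was removed, an alternative added after the data had been examined, 10056 genes differed, 8527 of them among those first called.

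**Figure D1:**
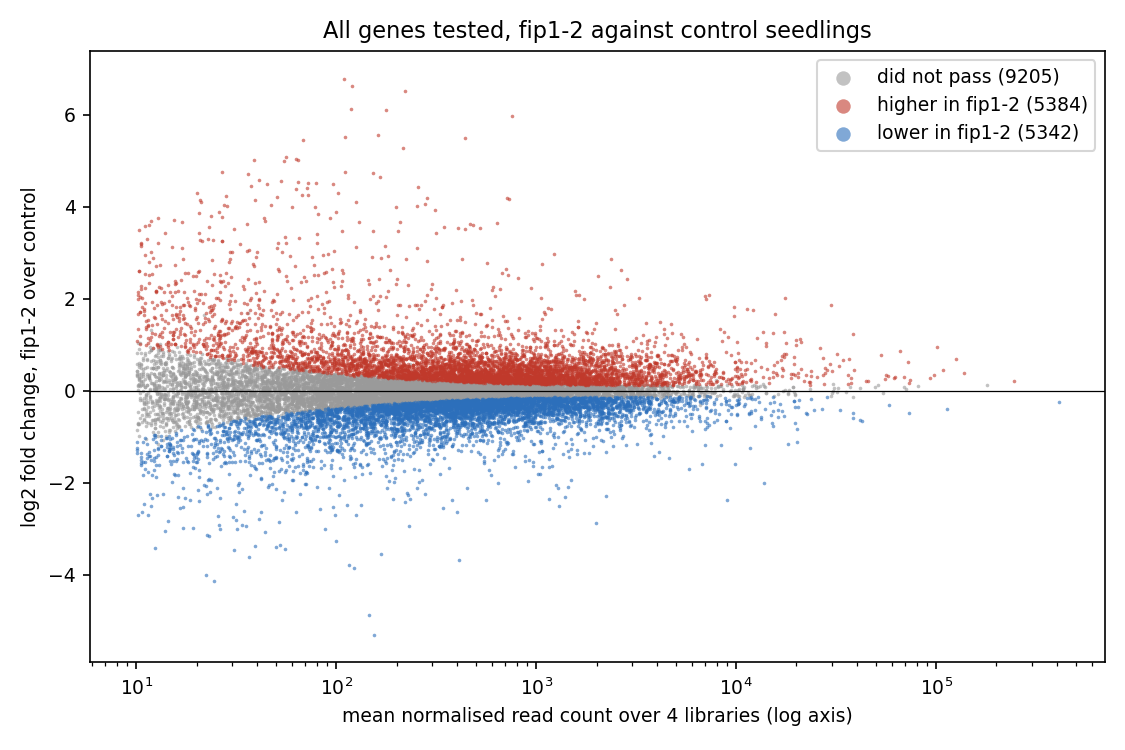
Each point is 1 of the 19931 genes tested, with its mean normalised read count over the 4 libraries on a log axis and its log2 fold change of fip1-2 over control on the linear axis; colours mark the 5384 genes higher in fip1-2, the 5342 lower and the 9205 that did not pass limma's test at an adjusted p of 0.05. Large rises reached above 6 on the log2 scale and were found at low to middle counts, while most genes lay close to 0.

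The largest rises included genes almost without reads in control. AT1G36240, of a ribosomal protein family, had no control read and stood at 212 and 226 in the fip1-2 libraries, at least 75.6-fold higher with a floor of 3 reads per control library. AT1G19565, an uncharacterized gene, had 1 control read and a ratio of 498 (95% counting interval 88.9 to 19694), and the nudix hydrolase gene NUDT24 (AT5G19470) had 3 control reads and a ratio of 163 (55.4 to 793). EPR1 (AT2G27380), a proline-rich extensin, went from 4.32 ± 6.11 to 438 ± 186, and SAG29 (AT5G13170), a senescence-associated gene, from 21.1 and 13.6 in the control libraries to 994 and 738 in those of fip1-2. The defensin-like gene AT1G13609 went from 3.88 ± 4.13 to 352 ± 60.2 and the cupin gene AT2G28490 from 9.63 ± 6.76 to 422 ± 137. The retrotransposon-related gene AT5G18636 rose with a log2 fold change of 5.52, and the remaining rises of the 10 largest were the seed genes CRC and OLEO1. The largest falls were those of TAT3 (AT2G24850), a tyrosine aminotransferase, from 302 ± 172 to 6.21 ± 5.89, and of FAMT (AT3G44860), a carboxyl methyltransferase, from 283 ± 109 to 7.72 ± 3.57. The defence genes PR2 and PR1 came next, followed by ACD6 (AT4G14400), an ankyrin repeat gene of defence, which fell from 764 ± 49.9 to 57.8 ± 7.83. CYP71B22, AT5G52790, AT1G15125, AGP13 and CAF1a, a deadenylase gene, fell with log2 fold changes of -3.54, -2.94, -2.88, -2.71 and -2.64. Passing limma's test was a condition of the rule that chose these genes, and their adjusted p was 1.11e-05 or less. The size of some depended on single libraries. Without control replicate 1 and without control replicate 2, log2 fold changes were 7.72 and 5.30 for EPR1 (6.51 with both), 5.32 and 6.89 for AT1G13609 (6.11), 5.91 and 4.65 for AT2G28490 (5.28), and -5.91 and -4.69 for TAT3 (-5.30). That of TAT3 was -4.49 without fip1-2 replicate 1 and -6.10 without fip1-2 replicate 2.

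Genes of the polyadenylation machinery rose by small amounts. Of 24 tested, 15 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 0.28. Beside FIP1, the poly(A) polymerase gene PAPS4 (AT4G32850) went from 1765 ± 62.0 to 2443 ± 45.9 and AT1G66500, of the cleavage complex, from 58.9 ± 0.427 to 138 ± 18.4, while AT5G10350, a gene of the RNA-binding protein family, fell with a log2 fold change of -0.62. As a group that includes FIP1, and that was not tested without it, they stood above the other genes (camera adjusted p = 0.0036 with a preset correlation of 0.01). The adjusted p = 0.491 with an estimated correlation was the highest over its alternatives, and the lowest was 0.00238. With the length and GC trend removed the median was 0.14 and the log2 fold change of PAPS4 0.24, both still past the threshold.

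Seed transcripts were the group that differed most. Of 10 members, 8 passed the filter and were tested. All 8 rose, over all genes and adjusted over the list alone, with a median log2 fold change of 4.51. A gene with control values near 0, such as OLEO1, passed the filter only through its fip1-2 values, so the filter favours rises in this count. The cruciferin gene CRC (AT4G28520), for a seed storage protein, went from 29.3 ± 34.6 to 1477 ± 1150, and the oil body gene OLEO1 (AT4G25140) from 4.35 ± 0.714 to 317 ± 154, and OLEO2 (AT5G40420) rose with a log2 fold change of 4.52. PER1 (AT1G48130), a seed peroxiredoxin gene, went from 11.6 ± 2.65 to 238 ± 83.8. The storage albumin gene SESA3 had no control read and was at least 9.56-fold higher, and the median stayed 4.51 with it at that bound. The median was 3.80 without fip1-2 replicate 1, 5.11 without fip1-2 replicate 2, and 5.51 and 3.58 with pseudocounts of 0.5 and 8. The list passed camera at an adjusted p = 4.2e-05, and at an adjusted p = 0.491 with an estimated correlation it did not, the highest over its alternatives. The libraries differed within groups: the 8 genes took 0.00125% and 0.000313% of the normalised reads in the control libraries and 0.0243% and 0.00901% in the fip1-2 libraries. CRC, at 2290 and 664 in the fip1-2 libraries, lost its call under robust variance estimation (adjusted p = 0.0993, the highest over its alternatives). Its log2 fold change of 5.98 was 7.49 and 4.47 without control replicates 1 and 2, 5.09 and 6.87 without fip1-2 replicates 1 and 2, and 5.23 with the length and GC trend removed. SESA1, SESA2 and SESA3 are close copies whose reads the counting could split.

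Genes that respond to abscisic acid moved in both directions. Of 35 tested, 20 rose, 8 fell and 7 did not pass, and adjusted over the list alone 22 rose and 8 fell. RD22 (AT5G25610) went from 6896 ± 195 to 28032 ± 1664, KIN1 (AT5G15960) from 195 ± 46.5 to 1145 ± 171, RD29B (AT5G52300) rose with a log2 fold change of 4.19, and the receptor gene PYL4 (AT2G38310) fell from 3026 ± 125 to 1622 ± 74.8. The list rose on balance (median 0.45, camera adjusted p = 0.0107). The adjusted p was 0.596 with an estimated correlation, the highest over its alternatives, and 0.0585 by fry. The seed transcripts described above were higher in the same libraries. Among 17 regulators of salt, drought and cold responses, 5 rose and 5 fell, or 6 and 5 adjusted over the list alone: COR15A (AT2G42540) went from 2670 ± 403 to 11214 ± 1892, GOLS2 and the sodium transporter gene NHX2 rose with log2 fold changes of 1.15 and 0.83, and the zinc finger gene STZ (AT1G27730) fell from 452 ± 97.1 to 157 ± 10.9. That list had no call (camera adjusted p = 0.793), with a median of 0.01 and an upward test against a mean of -0.05. Heat shock genes rose in 5 of 7 cases and fell in 1, as adjusted over the list alone, with a median of 1.202. HSP18.2 (AT5G59720) went from 38.7 ± 8.47 to 297 ± 11.5, HSP90.1 from 269 ± 8.78 to 625 ± 70.0 and HSP17.4 from 8.22 ± 2.11 to 49.5 ± 3.92, while HSA32, at a log2 fold change of 0.92, lost its call with DESeq2 (adjusted p = 0.0589, the highest over its alternatives). The heat shock list was called (camera adjusted p = 0.0194, and adjusted p = 0.491 with an estimated correlation, the highest over its alternatives, the lowest being 0.00564). With a filter of 50 in place of 10 its median was 0.64 and adjusted p = 0.136.

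Genes induced by iron shortage rose strongly. Of 7 tested, 6 rose and AT2G28160, with a log2 fold change of -0.17, did not pass, and the counts were the same adjusted over the list alone. The regulator genes BHLH101 (AT5G04150) and BHLH39 (AT3G56980) went from 4.34 ± 2.02 to 140 ± 7.45 and from 8.68 ± 4.03 to 93.8 ± 15.2, and BHLH38 (AT3G56970), with 3 control reads, had a ratio of 55.5 (95% counting interval 18.7 to 272). IRT1 (AT4G19690), the root iron transporter gene, went from 143 ± 50.9 to 990 ± 382. The median was 2.77 (camera adjusted p = 0.0013), with an adjusted p = 0.491 with an estimated correlation as the highest over its alternatives. Nitrate genes split evenly, with 9 rises and 9 falls among 26, or 9 and 10 adjusted over the list alone (camera adjusted p = 0.805). The glutamate synthase gene GLT1 (AT5G53460) went from 11672 ± 503 to 23831 ± 113, and NRT3.1, RFNR2 and the nitrite reductase gene NIR1 rose with log2 fold changes of 1.24, 0.80 and 0.52. GLT1, with a log2 fold change of 1.03, stood at 0.32 once the length and GC trend was removed. Of 6 phosphate starvation genes, 2 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.793). The transporter gene PHT1;1 rose from 2369 ± 129 to 3681 ± 542 and SPX1 and IPS1 fell with log2 fold changes of -0.89 and -1.24. PHO1;H1, at 0.44, lost its call with DESeq2 (adjusted p = 0.0637, the highest over its alternatives) and without fip1-2 replicate 2 (0.0505).

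**Figure D2:**
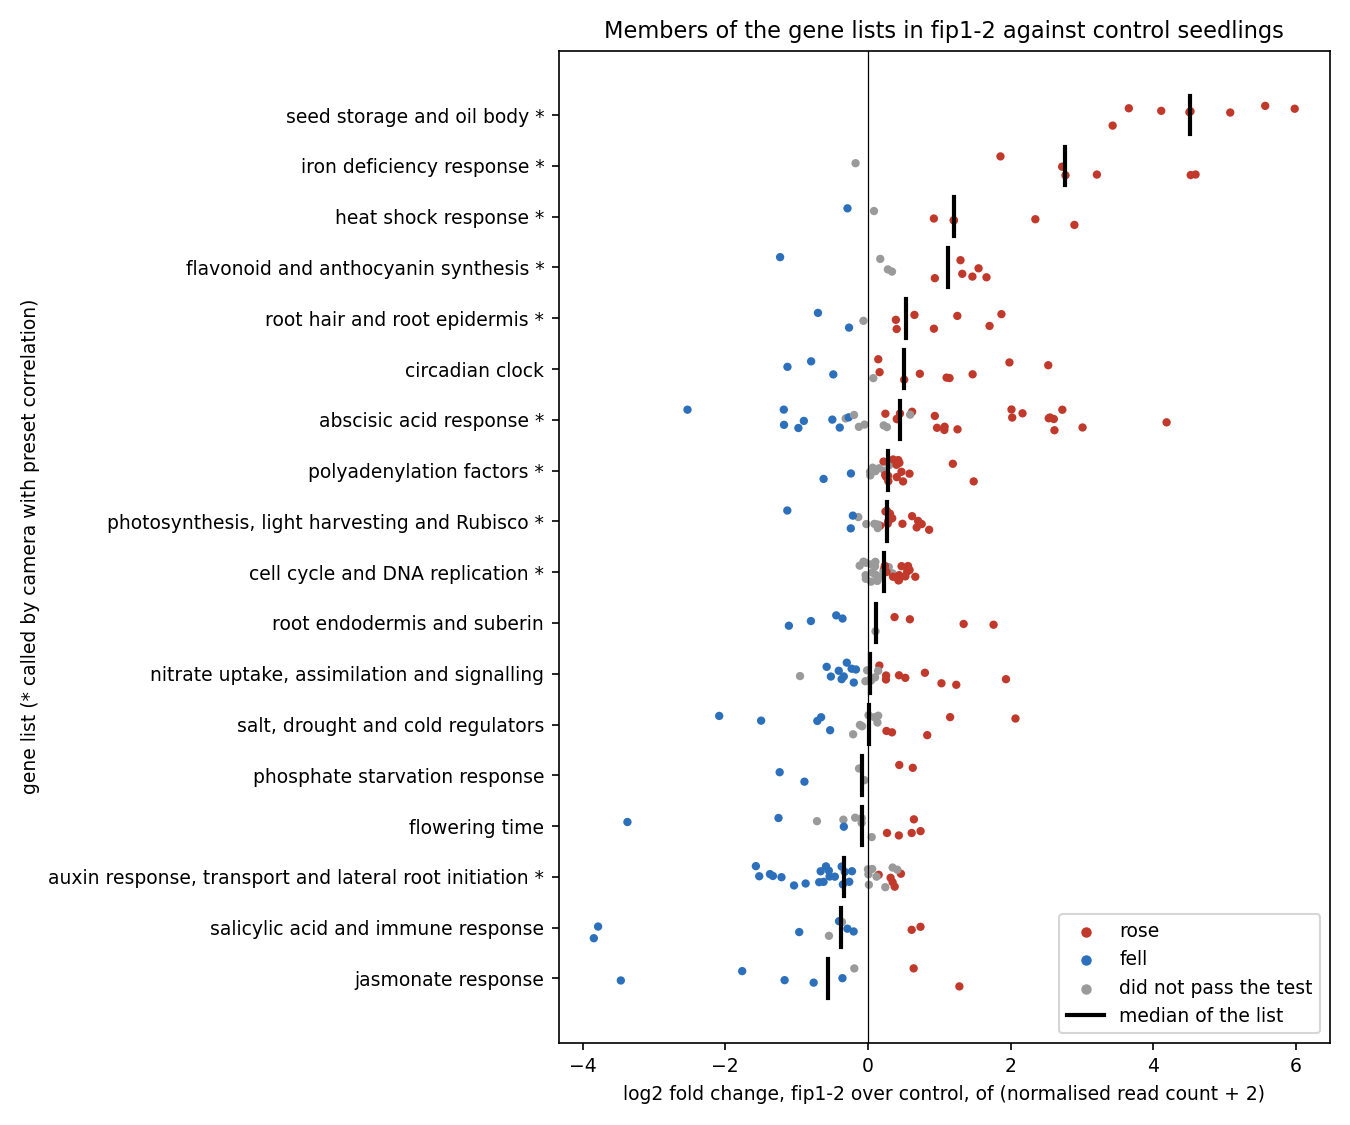
Points are the tested members of the 18 gene lists, placed by their log2 fold change of fip1-2 over control and coloured by whether they rose, fell or did not pass limma's test at an adjusted p of 0.05; black bars are list medians and asterisks mark the 10 lists called by camera with a preset correlation. The seed list lies farthest to the right with a median of 4.51, and the auxin list, at -0.34, is the called list whose median lies below 0.

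Auxin-response genes were lower in fip1-2. Of 32 genes of auxin response, transport and lateral root initiation, 19 fell, 5 rose and 8 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was -0.34. The auxin-induced repressor genes IAA19 (AT3G15540) and IAA2 (AT3G23030) fell from 1485 ± 18.3 to 589 ± 31.7 and from 4535 ± 71.1 to 2825 ± 119, and GH3.3 (AT2G23170) and GH3.5 (AT4G27260), for enzymes that conjugate auxin, from 1969 ± 175 to 757 ± 28.2 and from 4412 ± 120 to 3016 ± 52.7. The list was called downward (camera adjusted p = 0.00416, and adjusted p = 0.491 with an estimated correlation, the highest over its alternatives, the lowest being 0.000222). Of 32 cell cycle and DNA replication genes, 14 rose and 18 did not pass, as adjusted over the list alone. CYCD3;1 (AT4G34160), a cyclin gene of cell cycle entry, went from 663 ± 49.1 to 979 ± 71.0, and the replication licensing genes MCM4, MCM5 and MCM7 rose with log2 fold changes of 0.66, 0.47 and 0.44. This list, with a median of 0.23, was called (camera adjusted p = 0.0133, and adjusted p = 0.596 with an estimated correlation), and over its alternatives adjusted p ran from 0.00465 to 0.596. Without control replicate 1 it was 0.0609, without control replicate 2 it was 0.331 and by fry 0.0585.

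Markers of root hairs and root epidermis rose in 7 of 10 cases and fell in 2, with the same counts adjusted over the list alone. The wall protein genes PRP3 (AT3G62680) and LRX1 (AT1G12040) rose, the former with a log2 fold change of 1.87 and the latter from 507 ± 1.11 to 1671 ± 331. The expansin gene EXPA7 went from 214 ± 14.8 to 513 ± 31.7 and EXPA18 from 211 ± 10.4 to 405 ± 66.2. The list, with a median of 0.53, was called (camera adjusted p = 0.0194, and adjusted p = 0.596 with an estimated correlation, the highest over its alternatives). Of 9 endodermis and suberin markers, 4 rose and 4 fell, as adjusted over the list alone. The patterning genes SHR (AT4G37650) and SCR (AT3G54220) went from 364 ± 37.5 to 923 ± 52.3 and from 579 ± 20.6 to 873 ± 55.4, and CASP5 and CASP1, of the Casparian strip, rose with log2 fold changes of 1.76 and 0.37. That list had no call on balance (median 0.11, from -0.13 without the filter or with a filter of 50 to 0.26 with the trend removed, camera adjusted p = 0.679), but passed fry (0.00467, the lowest over its alternatives, the highest being 0.858).

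Shoot markers rose in the same libraries. Of 22 photosynthesis genes, 14 rose and 3 fell, or 14 and 4 adjusted over the list alone. PSBO2 (AT3G50820), of photosystem II, went from 12587 ± 304 to 21218 ± 473, and the light-harvesting genes LHCB2.2 and LHCA1 rose with log2 fold changes of 0.68 and 0.70. The close copies LHCB1.1 and LHCB1.2 rose with log2 fold changes of 0.86 and 0.62, while LHCB1.3, the most abundant of the 3, fell from 443786 ± 18045 to 375480 ± 6927. Summed, the 3 copies stood at 547776 ± 18139 in control and 548092 ± 11334 in fip1-2, and the counting could split their reads, so the rises of LHCB1.1 and LHCB1.2 are uncertain. The list was called (median 0.27, camera adjusted p = 0.00416, and adjusted p = 0.596 with an estimated correlation), and over its alternatives adjusted p ran from 0.00131 to 0.596. It was 0.196 after quantile normalization, where the median was 0.03 and the log2 fold change of LHCA1 0.31, and 0.117 without control replicate 2. Chloroplast and mitochondrial genes together took 2.18% and 2.21% of the reads in the control libraries and 2.47% and 2.41% in the fip1-2 libraries, a difference of 0.243 percentage points between the means. With 2 libraries against 2, an exact permutation test cannot go below p = 0.333. Flavonoid and anthocyanin genes rose in 6 of 10 cases and fell in 1, or 7 and 1 adjusted over the list alone. The chalcone synthase gene CHS (AT5G13930) went from 754 ± 1.36 to 1889 ± 25.5, F3H and TT19 rose with log2 fold changes of 1.55 and 1.66, and the regulator gene MYB12 (AT2G47460) fell from 77.8 ± 10.8 to 31.9 ± 4.08. The list, with a median of 1.12, was called (camera adjusted p = 0.0194, and adjusted p = 0.596 with an estimated correlation, the highest over its alternatives, the lowest being 0.00371). With a filter of 50 its median was 0.31 and adjusted p = 0.135, and without fip1-2 replicate 1 they were 0.69 and 0.0777. Without the filter the median was 0.67.

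Of 10 salicylic acid and immune genes, 6 fell and 2 rose, or 7 and 2 adjusted over the list alone. PR2 (AT3G57260) and PR1 (AT2G14610), classical markers of the salicylic acid response, went from 232 ± 183 to 11.9 ± 3.76 and from 218 ± 172 to 12.9 ± 9.60, the regulator gene WRKY70 (AT3G56400) fell with a log2 fold change of -0.96, and ICS1 (AT1G74710), of salicylic acid synthesis, rose with one of 0.74. The control libraries differed widely, at 103 and 362 for PR2 and 96.1 and 340 for PR1. Both genes lost their calls under robust variance estimation (adjusted p = 0.0606 and 0.103, the highest over the alternatives of each). Without control replicates 1 and 2, log2 fold changes were -4.74 and -2.94 for PR2 (-3.84 with both) and -4.68 and -2.88 for PR1 (-3.78), and for PR1 they were -3.08 and -4.49 without fip1-2 replicates 1 and 2. The list had no call (median -0.38, camera adjusted p = 0.0825), though without control replicate 1 it passed at 0.0160, the lowest over its alternatives, whose highest was 0.596. Jasmonate genes fell in 5 of 8 cases and rose in 2, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.210). LOX2 (AT3G45140) and VSP2 (AT5G24770) rose from 10111 ± 854 to 24688 ± 3892 and from 1336 ± 130 to 2079 ± 66.1, while the repressor genes JAZ1 and JAZ10 fell with log2 fold changes of -0.76 and -1.76.

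Flowering time genes split between 5 rises and 3 falls among 14, as adjusted over the list alone (camera adjusted p = 0.962). The floral repressor gene FLC (AT5G10140) fell from 72.9 ± 8.04 to 5.65 ± 3.59 and FLM (AT1G77080) from 439 ± 11.2 to 185 ± 43.5. FPA (AT2G43410) and FCA (AT4G16280), RNA-binding regulators of the autonomous flowering pathway, rose from 772 ± 25.8 to 1181 ± 24.0 and from 521 ± 2.41 to 816 ± 19.9, with log2 fold changes of 0.61 and 0.64 that stood at 0.30 and 0.28 once the length and GC trend was removed. Clock genes, included as a check on the time of harvest, rose in 9 of 13 cases and fell in 3, as adjusted over the list alone. The morning gene LHY (AT1G01060) went from 21.2 ± 1.21 to 132 ± 17.0 and LNK2 (AT3G54500) from 478 ± 6.88 to 1057 ± 11.4, and the evening genes TOC1 (AT5G61380) and ELF4 (AT2G40080) fell from 4487 ± 78.3 to 2583 ± 49.4 and from 780 ± 74.2 to 355 ± 30.3. The clock list was not called on balance (median 0.51, camera adjusted p = 0.0615). With a filter of 50 the median was 0.34. The list passed without the filter (0.0388), without a variance trend (0.0366) and by fry (0.00379), and over its alternatives adjusted p ran from 0.00379 to 0.491.

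**Figure D3:**
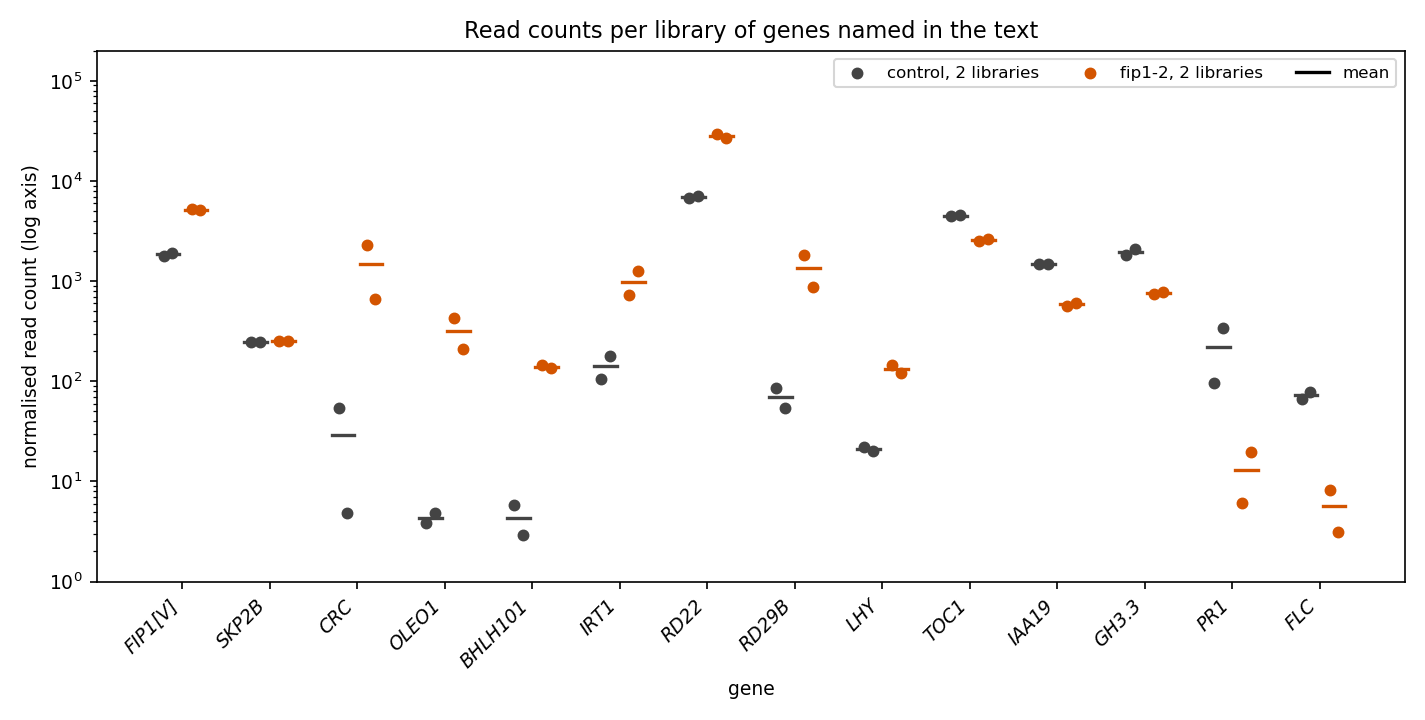
Normalised read counts per library, on a log axis, of 14 genes named in the text, with grey points for the 2 control and orange points for the 2 fip1-2 libraries and short lines for the group means. The replicates of FIP1[V], SKP2B, IAA19 and TOC1 lie close together, while CRC, from 664 to 2290 in fip1-2, and PR1, from 96.1 to 340 in control, vary between libraries of one group.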

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

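Removal of the length and GC trend was chosen after the data had been examined; the other alternatives were planned. The count of 10726 genes stayed within 1.5 times under other pseudocounts, filters, scalings, variance priors and edgeR, and ran from 8547 to 9823 with 1 library left out, where the lone library of a group is assumed to vary like the other group. DESeq2 called 7007 genes, 3329 of them lower, and the cause was not tested. A 2-fold minimum left 1673 genes, 924 higher and 749 lower, because most differences are smaller than that. Estimating the correlation left 0 lists by camera, and 0 at an unadjusted p under 0.05, against 10 by fry. That setting changes the correlation and the degrees of freedom together. For the iron and heat shock lists the estimated correlations, 0.0055 and -0.034, lay below the preset 0.01. These values argue against a higher correlation as the reason that those lists lost their calls. For the other called lists the parts were not separated. The mitochondrial genes alone differed by 0.00554 percentage points in their share of reads, since they take a small part of the organelle total. The replicate numbers did not pair the libraries (correlation of the deviations of same-numbered libraries -0.012), and a fit with the replicate block called 11004 genes; with it the cell cycle and photosynthesis lists had no call and the salicylic acid list gained one. FIP1 kept its direction and call in all alternatives, with log2 fold changes of 1.01 (length and GC trend removed) to 1.53. Of the 88 other named genes, 86 kept their side of the threshold with DESeq2, 85 with robust variance estimation, 87 without fip1-2 replicate 2, and all that were tested did so under each other alternative. Most of the named genes were chosen for large folds or small p in these data, which favours keeping their calls. Of all 10726 genes called by limma, DESeq2 also called 64.5% and robust variance estimation 99.3%. Without a variance trend the share was 76.0%. The fold change of 6 named genes moved by over 1.5 times with a pseudocount of 0.5. That of 15 did so with one of 8, since the pseudocount sets the fold where one group has few reads. Robust variance estimation was not run for the list tests, since camera has no such option. At this depth 38% of the simulated genes with the smallest change were recovered. Far more genes were called in the data than were changed in the simulation. The share of 38% therefore does not measure how many small differences the real comparison missed.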

Other observations

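The tests of gene groups, of the clock, of both seed explanations and of neighbour orientation, expression and distance were chosen after results that bear on them had been seen, as were the genes named here. Gene groups were genes that share a product description in the reference, with at least 10 tested members. Of 192 groups, 7 held more rises and 5 more falls than other tested genes. The test treats genes as independent, which members of one family need not be. Its p-values do not measure the spread between libraries. Genes for proline-rich extensins, structural proteins of the cell wall, rose in 10 of 11 cases where 2.97 were expected (one-sided Fisher's exact test, adjusted p = 0.00164 over 384 tests). EXT12 went from 567 ± 15.7 to 4150 ± 675 (SD, n = 2), EXT6 from 725 ± 20.7 to 4555 ± 943 and AT1G23720 from 2816 ± 236 to 11307 ± 990. These genes have repetitive, similar sequences whose reads the counting could split. Late embryogenesis abundant genes, of drying seeds, rose in 9 of 10 cases (Fisher's exact test, adjusted p = 0.00443). AT3G02480 went from 20.8 ± 4.93 to 375 ± 163 and LEA7 from 28.9 ± 6.62 to 597 ± 532. As in the seed list, a gene near 0 in control can pass the filter only through its fip1-2 values, which favours rises. How many members did so was not counted. Subtilase genes rose in 12 of 16 cases (0.00477), MATE efflux carrier genes in 22 of 42 (0.0193) and other proline-rich family genes in 12 of 18 (0.0193). Genes of the integrase-type DNA-binding superfamily, which holds the ERF transcription factors, fell in 26 of 49 cases (0.00477), such as AT5G61590, from 5553 ± 298 to 3229 ± 29.9, while ANT, one of 5 that rose, went from 350 ± 19.3 to 790 ± 69.3. These 6 groups passed again after the length and GC trend was removed. The other 6 of the 12 called groups did not, among them the auxin-responsive SAUR-like genes, which have short transcripts: 34 of 54 fell, and 16 after removal, where 14.3 were expected. The dirigent-like genes missed the threshold narrowly, with 12 of 18 falling before and 11 after removal (adjusted p = 0.0576).

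Of the tested genes, 53.8% differed between the groups. A trend of the fold change with transcript length and GC content is argued against as the whole cause, because the calls after its removal were 0.9375 of the calls before, with 8527 in common, of which 84 changed sign. A shift in the time of day at harvest may contribute: all 7 morning clock genes rose, 3 of 4 evening clock genes fell, and the medians differed by 1.785 on the log2 scale. The other 2 clock genes, GI and PRR5, which peak between these, rose with log2 fold changes of 0.16 and 0.14, and counted as evening genes they brought the difference to 1.35. With every library of a genotype on one side, a shifted harvest and an effect of fip1-2 on the clock both stay open, and so does a direct effect of the mutation on the other genes.

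The rise of the seed transcripts varied between the fip1-2 libraries, all 8 genes being higher in replicate 1, with log2 ratios from 0.28 for OLEO2 to 2.45 for SESA2. One source of seed RNA with a fixed make-up, present in different amounts, is argued against, because these ratios had an SD of 0.8119, against a median of 0.176 in 10000 random sets of genes matched on level (permutation p = 0.0001, the smallest they can give). Seeds or seedlings at mixed stages and delayed germination caused by the mutation stay open and were not tested. Whether seed material brought the rise of the abscisic acid list cannot be told apart from a response of the seedlings. The seed genes share no single ratio to compare with. Of the 20 members that rose, 5 had a ratio of their excess over control below that of every seed gene. The others lay within the range of the seed genes, with log2 ratios up to 2.13 for TSPO.

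FIP1 acts at the 3' ends of transcripts, so genes with a mean of 10 to 100 were compared by their upstream neighbour, within 500 bp and with a mean of at least 100, in 1 of 7 comparisons of neighbours (two-sided permutation tests). These tests shuffle genes as if they were independent, and their p-values do not measure the spread between libraries. The median log2 fold change was 0.11 for 695 genes behind a neighbour on the same strand and -0.03 for 363 with a divergent neighbour, a difference of 0.1386 (permutation p = 0.00247, adjusted 0.00864), and for the 695 genes it was 0.13 higher than for 293 with such a neighbour beyond 2000 bp (permutation p = 0.0262, adjusted 0.0458), while among genes with a same-strand neighbour of any level within 500 bp it was 0.15 higher for the 350 behind the upper than for the 350 behind the lower tercile of neighbour expression (permutation p = 0.0230, adjusted 0.0458). A trend with length and GC content is argued against, since the difference was 0.1377 after removal (permutation p = 0.00115, adjusted 0.00805). Transcription running past the end of the upstream gene may add reads, but in 323 and 169 pairs that did not overlap and whose upstream gene changed by under 0.25 on the log2 scale the difference was 0.04194 (permutation p = 0.561), so a change of the upstream gene itself also stays open. No difference passed for genes with a mean of at least 1000 (0.02, permutation p = 0.301) or by the downstream neighbour (-0.06, permutation p = 0.145), and in 14 classes of control level and distance the same-strand genes were higher in 11, with differences from -0.52 to 0.92.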
